A study of Homo sapiens with 21 samples.

How the data were processed

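Total RNA of the HepG2-derived cells was extracted with QIAzol and RNeasy columns, and libraries were made with a SMARTer kit, per the labels, which do not state the strand. The authors aligned reads to GRCh38 with HISAT2 2.0.5, counted them with featureCounts 1.5.0-p3 and deposited FPKM values in a separate file for each of 6 groups, covering 6 unexposed libraries and 3 of each of 5 exposures. The labels state neither how FPKM were scaled nor which genes were kept in each table. In each of the 21 libraries FPKM times gene length was a whole multiple of one step to within 0.1 of a read, which gave read numbers back. The total implied by the scaling was 1.03 to 1.08 times the recovered reads in unexposed libraries and 0.942 to 1.01 times in exposed ones. This part of the scaling thus differed between exposed and unexposed libraries. Median-of-ratios factors lay at 1.0019 to 1.012, so the tables were used on their common scale. Rescaling by these factors, among the other settings below, could thus change little. Of 28808 genes 23375 were in all tables, and an absent gene was taken as 0. Of the 5433 others 45 would have passed the filter below, none of them protein-coding.

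Recovered reads ran from 15.2 to 24.35 M per library. With 3 libraries per exposure and the pooled spread, 95% intervals reached a median of 0.158 to either side on the log2 scale against unexposed cells and 0.183 between exposures.

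Genes with FPKM of at least 1 in at least 3 libraries were tested on log2(FPKM + 1), so that folds are of FPKM + 1, with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), by group means over all 21 libraries and moderated t statistics with a mean-variance trend. Benjamini-Hochberg adjustment was made within each comparison, and genes were called at an adjusted p under 0.05. The comparisons were each exposure against unexposed cells, each mixture against each of its components, AMPA against glyphosate, and both interactions, defined as mixture plus unexposed minus the single exposures. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted within each exposure, and again with an estimated correlation. The tests, gene lists, rule for naming genes and the first group of other settings below were fixed before the data were examined.

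The rule named, per exposure, the 5 protein-coding genes with the largest increase and the 5 with the largest decrease among those called whose libraries did not overlap. It named 3 each way for other comparisons, without the overlap condition for interactions, and where none passed the 3 each way with the smallest p. It also named up to 4 members of each called list by smallest p (3 of these members are not reported here), 5 genes each way for the overlap of exposures, and CYP1A1, CYP2B6, CYP3A4, PDK4, CPT1A, HMOX1 and CDKN1A always.

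Overlap was compared with 20 simulations without effect, in which exposed and unexposed values alike were drawn independently around the mean of each gene. It was also compared with fold changes taken against separate sets of 3 unexposed libraries. Opposite-strand genes were those whose exons overlap by at least 50 bp an oppositely transcribed gene of at least 50 FPKM and 20 times their own level.

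The procedure was tested on simulated data made from these libraries. All simulated libraries took the spread within the exposed groups, so the difference between unexposed replicates 1 to 3 and 4 to 6 was left out. The recovered shares below hold for that spread and may be too high for the real libraries. At 2-fold it recovered 85.8% of changed genes for glyphosate against unexposed cells, 82.7% for AMPA against glyphosate, 81.8% for AMPA+2,4-D against AMPA and 77.6% for an interaction, with 3.22 to 6.41% false calls. At 1.25-fold the shares were 53.4%, 40.9%, 44.2% and 23.9%. A simulated 1.5-fold shift of the heat shock list was called in 5 of 5 runs, with 0 calls among 24 other lists by camera. Simulated genes were drawn independently, so the correlation between genes was left out. The list result thus does not show how often lists are called by chance in the real libraries.

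Other settings tried were a pseudocount of 0.1, no filter, median-of-ratios scaling, TPM, fits of the compared groups alone, replicate number as a block, limma arrayWeights, each library left out in turn, and the list test with an estimated correlation. Added after the data were seen were voom on recovered reads, the removal of either set of unexposed libraries or of AMPA+2,4-D replicates 1 and 3, removal of a GC and length trend per library, and TPM with the genes tested held to the same 13405, since 17674 passed the filter on TPM. The estimation of array weights stopped before convergence.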

Results

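RNA sequencing measured gene expression in a clonal derivative of the human hepatoma line HepG2, in 21 libraries from 6 groups. Unexposed cells gave 6 libraries, and 3 libraries came from each of 5 exposures lasting 48 h. Glyphosate, a broad-spectrum herbicide, was given at 5.6 µM (0.95 µg/mL), its breakdown product AMPA (aminomethylphosphonic acid) at 34 µM (3.7 µg/mL), and the auxin-type herbicide 2,4-D at 2.5 µM (0.56 µg/mL). The other 2 exposures combined glyphosate with 2,4-D and AMPA with 2,4-D, each compound at the concentration used alone. Per the labels these concentrations lay 1000-fold below the IC50 for viability, and the title of the series asks how combined exposures compare with individual ones. Libraries held 15.2 to 24.35 M reads recovered from the FPKM values, with 17.41 to 19.77 M in unexposed cells. Of 28808 genes listed, 13405 were tested, 10512 of them protein-coding. The labels do not say whether replicates were separate cultures, so the p-values of single genes measure the spread between these libraries. Those of gene lists and of Fisher's exact test compare genes with genes.

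**Figure D1:**
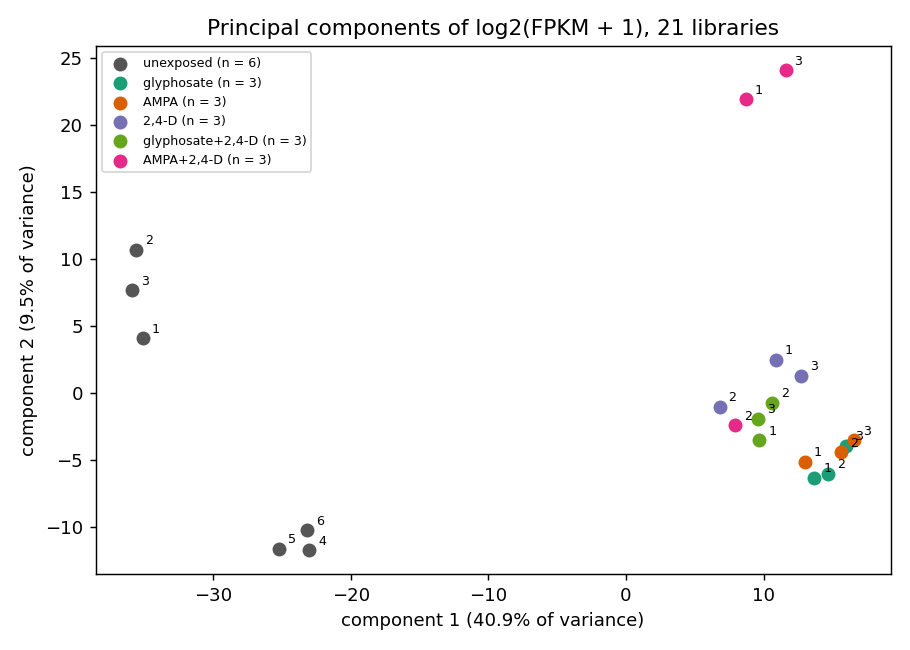
First and second principal components of log2(FPKM + 1) over 21 libraries, with the share of variance on each axis; each point is a library, coloured by group and numbered by replicate. Component 1 (40.9% of variance) parts unexposed from exposed libraries, unexposed replicates 1 to 3 lie apart from 4 to 6, and AMPA+2,4-D replicates 1 and 3 lie apart from replicate 2.

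The unexposed libraries formed a pair of sets. Between replicates 1 to 3 and 4 to 6, squared differences per gene were 29.3 to 41.0 times those from read counting alone, against 3.93 to 5.96 within the first set and 3.45 to 4.54 within the second. Limma called 4239 genes between these sets, and 0 in each of the other 9 ways to part them 3 against 3. Exposed libraries lay 57.8 to 104 times counting noise from unexposed replicates 1 to 3 and 26.5 to 60.5 times from replicates 4 to 6. Among exposed libraries of different groups the value was 2.88 to 18.7. The labels name no batch, so no exposed library could be matched to either set, and exposure cannot be told apart from a batch shared by the exposed libraries.

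In cells given glyphosate, IGFBP3 and DKK1 were the genes with the largest increase and UCP2 the gene with the largest decrease among those the rule named. IGFBP3 (ENSG00000146674, GRCh38 chromosome 7, 45912245 to 45921874), which binds insulin-like growth factors, went from 2.63 ± 1.72 FPKM (SD, n = 6) in unexposed cells to 23.9 ± 2.92 (SD, n = 3), a log2 change of 2.91 ± 0.29 (SE). DKK1 (ENSG00000107984, chromosome 10, 52314296 to 52318042), a secreted WNT antagonist, rose by 2.87 ± 0.29, and the scaffold gene AKAP12 by 2.41 ± 0.17. CYR61, a matricellular protein gene also called CCN1, rose by 2.26 ± 0.08 and SLC2A3, a glucose transporter gene, by 2.21 ± 0.10. UCP2 (ENSG00000175567, chromosome 11, 73974667 to 73983307), a mitochondrial carrier gene, went from 16.1 ± 4.51 (SD, n = 6) to 3.68 ± 0.501 FPKM (SD, n = 3), a log2 change of -1.83 ± 0.17. KLHDC7B (-1.72 ± 0.10), FNDC4 (-1.68 ± 0.26), the glutathione transferase gene GSTA1 (-1.63 ± 0.21) and the aldo-keto reductase gene AKR1B10 (-1.61 ± 0.38) were also lower. The 3 glyphosate libraries lay outside all 6 unexposed ones for each of these genes, and the limma adjusted p was at most 0.00162. GSTA1 rested on 17 to 25 reads per glyphosate library and shares near-identical sequence with GSTA2. Limma called 7069 of 13405 genes, 3708 higher and 3361 lower, 343 of them by at least 2-fold in FPKM + 1 (821 with a pseudocount of 0.1), and 45.5% of genes had no overlap between groups, where chance gives 2.38%. After rescaling to TPM, under which 17674 genes passed the filter, 37.3% of called genes were higher, against 52.5% before it, and 37.6% with the same 13405 genes tested.

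With AMPA, 8 of the 10 genes named were those named with glyphosate. DKK1 went from 4.80 ± 2.74 FPKM (SD, n = 6) to 40.2 ± 6.88 (SD, n = 3), a log2 change of 2.96 ± 0.29 (SE), and IGFBP3 rose by 2.91 ± 0.29. AKAP12 (2.48 ± 0.17), CYR61 (2.31 ± 0.08) and ANKRD1 (2.30 ± 0.07), which encodes an ankyrin repeat protein of muscle and stressed cells, were also higher. UCP2 (-1.77 ± 0.17), KLHDC7B (-1.72 ± 0.10), FNDC4 (-1.66 ± 0.26), the WNT antagonist gene DKK4 (-1.64 ± 0.21) and GSTA1 (-1.58 ± 0.21) were lower. Each of these 10 genes separated all 3 AMPA libraries from all 6 unexposed ones. Limma called 7083 genes, 3758 higher and 3325 lower, 332 by at least 2-fold, with 44.4% of genes free of overlap. The share of called genes that were higher was 53.1%, and 29.4% after rescaling to TPM (29.9% with the same genes tested). The median log2 change over the same 13405 genes was 0.01 before rescaling and -0.14 after it.

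For 2,4-D the changes were of similar kind. DKK1 rose by 2.62 ± 0.29 (log2, SE) to 31.2 ± 1.81 FPKM (SD, n = 3), IGFBP3 by 2.59 ± 0.29, AKAP12 by 2.27 ± 0.17 and CYR61 by 2.15 ± 0.08. HSPA6, an inducible heat shock protein gene, went from 1.35 ± 0.278 FPKM (SD, n = 6) to 9.48 ± 2.12 (SD, n = 3), a log2 change of 2.14 ± 0.16. UCP2 (-1.62 ± 0.17), DKK4 (-1.60 ± 0.21), KLHDC7B (-1.46 ± 0.10), FNDC4 (-1.45 ± 0.26) and AKR1B10 (-1.43 ± 0.38) were lower in every 2,4-D library than in every unexposed one. Limma called 6379 genes, 3345 higher and 3034 lower, 225 by at least 2-fold, with 39.7% of genes free of overlap. Of the called genes 52.4% were higher, and 35.8% after rescaling to TPM.

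In cells given glyphosate with 2,4-D, HSPA6 led at 13.4 ± 4.71 FPKM (SD, n = 3), a log2 change of 2.57 ± 0.16 (SE). IGFBP3 (2.54 ± 0.29), DKK1 (2.47 ± 0.29), CYR61 (2.38 ± 0.08) and AKAP12 (2.23 ± 0.17) were higher too. KLHDC7B (-1.48 ± 0.10), UCP2 (-1.37 ± 0.17), the glycine transporter gene SLC6A9 (-1.36 ± 0.10), the monocarboxylate transporter family gene SLC16A13 (-1.31 ± 0.11) and AKR1B10 (-1.30 ± 0.38) were lower, the last not in a fit of the compared groups alone (limma adjusted p = 0.0673). Limma called 6445 genes, 3408 higher and 3037 lower, 218 by at least 2-fold, with 40.4% of genes free of overlap. The higher share was 52.9%, and 31.0% after rescaling to TPM.

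AMPA with 2,4-D gave DKK1 at 35.6 ± 1.92 FPKM (SD, n = 3), a log2 change of 2.81 ± 0.29 (SE). IGFBP3 (2.58 ± 0.29), HSPA6 (2.36 ± 0.16), AKAP12 (2.11 ± 0.17) and SLC2A3 (1.92 ± 0.10) were higher, while UCP2 (-1.76 ± 0.17), KLHDC7B (-1.59 ± 0.10), SLC16A13 (-1.42 ± 0.11), DKK4 (-1.39 ± 0.21) and LCN2 (-1.37 ± 0.15), which encodes the iron-siderophore carrier lipocalin 2, were lower. Limma called 6758 genes, 3491 higher and 3267 lower, 271 by at least 2-fold, with 39.3% of genes free of overlap. The higher share was 51.7%, and 32.1% after rescaling to TPM. With replicate 2 as the lone AMPA+2,4-D library, assumed to vary like the other groups, 3565 genes were called.

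**Figure D2:**
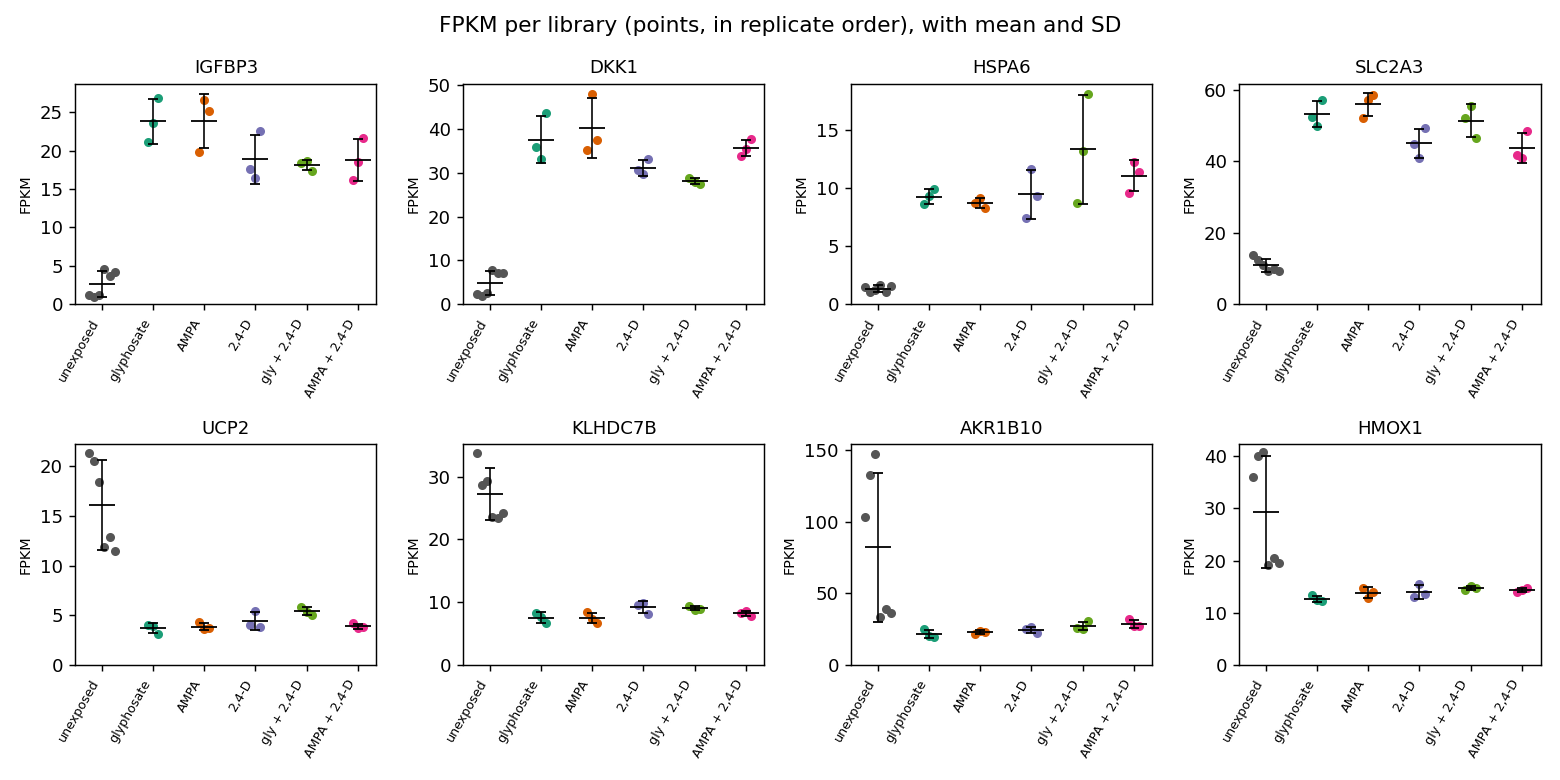
FPKM of 8 named genes per library, as points in replicate order within each of 6 groups, with the mean and SD of each group as bars. IGFBP3 lay at 0.879 to 4.65 FPKM in unexposed libraries and at 16.2 to 26.9 in exposed ones; AKR1B10 lay at 103 to 147 in unexposed replicates 1 to 3, at 33.2 to 39.2 in replicates 4 to 6 and at 19.5 to 31.9 in exposed libraries.

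Several of these genes also differed between the sets of unexposed libraries. IGFBP3 lay at 0.879 to 1.24 FPKM in unexposed replicates 1 to 3 and 3.65 to 4.65 in replicates 4 to 6, and AKR1B10 at 103 to 147 and 33.2 to 39.2. FNDC4 lay at 67.0 to 70.3 FPKM in the first set, 25.4 to 34.9 in the second and 11.7 to 18.5 in the exposed libraries.

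Of the genes named in advance, HMOX1, the stress-induced heme oxygenase, fell from 29.3 ± 10.7 FPKM (SD, n = 6) to group means of 12.6 to 14.7, log2 changes of -1.08 to -0.87 (SE 0.20). In unexposed replicates 1 to 3 HMOX1 lay at 36.0 to 40.8 FPKM and in replicates 4 to 6 at 19.2 to 20.4. CDKN1A, the cell-cycle inhibitor p21, had log2 differences of 0.18 to 0.34 (SE 0.05) and passed in all 5 exposures. After rescaling to TPM, CDKN1A did not pass with AMPA (0.14, limma adjusted p = 0.0646) or AMPA+2,4-D (0.07, 0.350), nor with the latter without its replicates 1 and 3 (0.233). CYP2B6, a target of the receptors CAR and PXR, rose by 0.22 to 0.48 (SE 0.06), and its call with glyphosate and 2,4-D was lost without replicate 3 of that group (limma adjusted p = 0.0534), after rescaling to TPM (0.227), without unexposed replicates 1 to 3 (0.117) and in a fit of the compared groups alone (0.0556). CYP1A1, a target of the aryl hydrocarbon receptor, had log2 differences of 0.43 to 0.66 (SE 0.25) and passed with glyphosate (limma adjusted p = 0.0311) and AMPA (0.0382). The exposed libraries overlapped unexposed replicates 1 to 3 (3.96 to 5.26 FPKM), and replicates 4 to 6 lay at 1.45 to 1.86. Leaving out unexposed replicate 4, 5 or 6, glyphosate replicate 1 or 3, or any AMPA replicate ended those CYP1A1 calls, with adjusted p up to 0.135 and 0.111, as did rescaling to TPM (0.0751 and 0.117) and leaving out unexposed replicates 4 to 6 together (at least 0.440). Without unexposed replicate 3, CYP1A1 passed in each of the 3 exposures with 2,4-D, with adjusted p down to 0.0442, 0.0190 and 0.0316, and without replicate 2 it passed in the pair of mixtures. Without unexposed replicates 1 to 3 together CYP1A1 also passed in those 3 exposures (log2 0.98 to 1.09, limma adjusted p = 1.86e-06 to 5.11e-06). Its calls thus depended on which unexposed set was used. CPT1A, the entry enzyme of mitochondrial fatty acid oxidation, passed with AMPA (0.18 ± 0.06, SE), but not without AMPA replicate 1 or 2 (adjusted p up to 0.0671) or after rescaling to TPM (0.763), and had 0.11 to 0.12 elsewhere. Without unexposed replicate 3, CPT1A also passed with glyphosate (0.0495) and 2,4-D (0.0416). Without unexposed replicates 1 to 3 together it passed with each exposure other than AMPA too (log2 0.21 to 0.23, limma adjusted p = 0.00151 to 0.00233). Without replicates 4 to 6 together its call with AMPA was lost (0.08, limma adjusted p = 0.112). CYP3A4 and PDK4 were too low to test, at 0 to 3 and 0 to 8 reads per library.

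Of 27 gene lists fixed before the data were examined, 25 had enough tested members, and camera with a preset correlation of 0.01 called 46 of 125 list and exposure pairs, 25 higher and 21 lower. With an estimated correlation 17 remained. Random draws of the groups gave a median of 36 calls at the preset correlation, so chance is not excluded for the count of 46. Ranges below run over the 5 exposures, counts are limma calls over all genes tested, and the ribosomal share of FPKM rose with the exposures, from 7.67 ± 0.518% (SD, n = 6) in unexposed cells to group means of 9.19 to 10.0%.

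Immediate early genes, which answer growth factors and stress within minutes, were higher, with 19 of 21 members called higher in every exposure, also when adjusted over the list alone, and list medians of 0.82 to 0.96. KLF10 rose by 1.30 to 1.49 (SE 0.08), the phosphatase gene DUSP1 by 0.92 to 1.33 (SE 0.07), JUNB by 1.02 to 1.37 (SE 0.08) and CYR61 by 1.86 to 2.38 (SE 0.08). Heat shock genes followed, with 18 to 19 of 21 members higher over all genes and 18 to 19 adjusted over the list alone, and medians of 0.44 to 0.59. The co-chaperone gene DNAJB1 rose from 39.3 ± 0.764 FPKM (SD, n = 6) to group means of 72.6 to 90.2, the chaperone genes HSP90AA1 by 0.85 to 0.99 (log2, SE 0.05) and HSPA1A by 1.38 to 1.67 (SE 0.11), and DNAJA1 by 0.60 to 0.74 (SE 0.05). HSPA1A shares near-identical sequence with HSPA1B. Both lists were called in all 5 exposures with the preset correlation (camera adjusted p from 7.35e-12 to 4.30e-08) and with an estimated correlation (adjusted p = 0.0111 to 0.0301 with an estimated correlation). Against each set of 3 unexposed libraries by itself, both lists were also called in all 5 exposures.

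Genes of glycolysis and the hypoxia response were higher as well, with 32 to 36 of 37 members called higher over all genes and 32 to 36 adjusted over the list alone, and medians of 0.77 to 0.93. PFKFB3, which makes an activator of glycolysis, went from 3.54 ± 0.323 FPKM (SD, n = 6) to group means of 9.68 to 13.3. SLC2A3 rose by 1.92 to 2.28 (log2, SE 0.10), the vasoactive peptide gene ADM by 1.03 to 1.37 (SE 0.06) and the histone demethylase gene KDM3A by 0.73 to 0.94 (SE 0.05). This list lost its calls with an estimated correlation (adjusted p = 0.0919 to 0.156 with an estimated correlation). Nuclear genes of oxidative phosphorylation were modestly higher, 28 to 37 of 49 over all genes and 28 to 39 adjusted over the list alone, with medians of 0.25 to 0.32. Of their members COX6A1 rose by 0.42 to 0.66 (SE 0.07), NDUFA4 by 0.49 to 0.67 (SE 0.06), COX4I1 by 0.29 to 0.46 (SE 0.04) and UQCRC1 by 0.21 to 0.45 (SE 0.03). Cytosolic ribosomal protein genes, a list included as a check on RNA quality, were higher in 66 to 73 of 74 members over all genes and 67 to 73 adjusted over the list alone, with medians of 0.39 to 0.55. RPS3A rose from 525 ± 41.9 FPKM (SD, n = 6) to group means of 755 to 841 and RPS4X by 0.48 to 0.63 (log2, SE 0.06), though ribosomal protein genes share sequence with many pseudogenes. The oxidative phosphorylation and ribosomal lists also lost their calls (adjusted p = 0.182 to 0.350 and 0.182 to 0.304 with an estimated correlation). The directions of these 3 lists held after rescaling to TPM, with medians of 0.67 to 0.84, 0.14 to 0.19 and 0.28 to 0.41.

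The unfolded protein and integrated stress response list was lower, with 30 to 33 of 44 members called lower over all genes and 30 to 33 adjusted over the list alone, and medians of -0.42 to -0.25. The endoplasmic reticulum proteins MANF and PDIA4 went from 125 ± 4.11 and 687 ± 45.2 FPKM (SD, n = 6) to group means of 78.2 to 85.7 and 420 to 469, and the stress protein gene NUPR1 fell with log2 changes of -1.14 to -0.76 (SE 0.08). ATF3, a transcription factor that is also on the immediate early list, rose by 0.72 to 1.02 (SE 0.06). The call held in all 5 exposures (adjusted p = 0.0202 to 0.0429 with an estimated correlation).

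Genes of fatty acid and triglyceride synthesis were lower in 12 to 17 of 27 members over all genes and 14 to 17 adjusted over the list alone, with medians of -0.33 to -0.18. GPAM, the first enzyme of triglyceride assembly, went from 37.6 ± 3.62 FPKM (SD, n = 6) to group means of 13.2 to 19.9. The lipid droplet gene PLIN4 changed by -1.10 to -0.84 (log2, SE 0.06), SREBF1, the lipogenic transcription factor, by -0.50 to -0.29 (SE 0.04) and AGPAT3 by -0.46 to -0.36 (SE 0.04). The list was called in 5 exposures, and in 2 with the other correlation (adjusted p = 0.0111 to 0.116 with an estimated correlation). Amino acid catabolism and urea cycle genes were lower in 15 to 18 of 31 members over all genes and 16 to 19 adjusted over the list alone, with medians of -0.33 to -0.21. The urea cycle gene ASS1 changed by -1.10 to -0.78 (SE 0.05), SARDH by -1.06 to -0.80 (SE 0.05) and MAT1A, which makes S-adenosylmethionine, by -1.03 to -0.75 (SE 0.07). These calls were lost in all 5 exposures (adjusted p = 0.0634 to 0.139 with an estimated correlation).

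Bile acid genes were called lower with AMPA+2,4-D and with glyphosate or 2,4-D alone, with 5 to 7 of 12 members lower over all genes and 5 to 8 adjusted over the list alone (adjusted p = 0.218 to 0.367 with an estimated correlation). Among them the reductase gene AKR1D1 changed by -1.52 to -1.10 (SE 0.11), the bile acid receptor FXR gene NR1H4 by -1.02 to -0.59 (SE 0.09), the FGF19 co-receptor gene KLB by -1.04 to -0.68 (SE 0.12) and NR0B2 by -0.39 to -0.24 (SE 0.09). NR0B2 lost its call with AMPA without AMPA replicate 3 (adjusted p = 0.0537), with AMPA+2,4-D without its replicate 3 (0.0843), and with glyphosate+2,4-D without any of its 3 replicates or unexposed replicate 4, 5 or 6 (up to 0.0967). Without unexposed replicates 4 to 6 together, NR0B2 passed with glyphosate alone among the 5 exposures (adjusted p of 0.0547 to 0.294 for the others). Against unexposed replicates 4 to 6 alone the bile acid list was called in 5 exposures, and against replicates 1 to 3 alone in 0 by camera.

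The NRF2 oxidative stress list was called lower with 2,4-D (camera adjusted p = 0.0356; adjusted p = 0.565 with an estimated correlation), with 11 to 14 of 30 members lower and 4 to 5 higher over all genes and the same ranges adjusted over the list alone. The cystine transporter gene SLC7A11 changed by -0.87 to -0.59 (SE 0.10), ABCC5 by -0.81 to -0.59 (SE 0.08) and TKT by -0.29 to -0.11 (SE 0.03). TKT lost its call with glyphosate+2,4-D without replicate 1 of that group (adjusted p = 0.0720), in a fit of the compared groups alone (0.0567) and with a GC and length trend removed (0.131). Against unexposed replicates 1 to 3 alone the NRF2 list was called lower in 5 exposures with medians of -0.58 to -0.51, and against replicates 4 to 6 alone in 0 by camera, with medians of 0.01 to 0.05.

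Mitochondrially encoded transcripts were called lower with glyphosate alone, with 8 of 13 members lower over all genes and 9 adjusted over the list alone, and a median of -0.49 (adjusted p = 0.277 with an estimated correlation). MT-CO3 changed by -0.65 to -0.26 (SE 0.06) over the 5 exposures, MT-ND1 by -0.61 to -0.34 (SE 0.08), MT-ND5 by -0.50 to -0.28 (SE 0.08) and MT-ATP6 by -0.49 to 0.02 (SE 0.09). MT-ATP6 passed with glyphosate and glyphosate+2,4-D, and in the latter not without replicate 1 or 2 (adjusted p up to 0.209) or without a filter on low values (0.169). Without that filter MT-CO3 did not pass in the mixtures with glyphosate and with AMPA either (0.0532 and 0.157). These transcripts took 23.4 ± 1.05% of FPKM in unexposed cells (SD, n = 6) and 20.2 ± 0.203% with glyphosate (SD, n = 3). The list medians with AMPA and AMPA+2,4-D were 0.00 and 0.02 while camera put them lower, without a call. Cholesterol synthesis genes were called lower with AMPA+2,4-D, 15 of 25 over all genes and 15 adjusted over the list alone (adjusted p = 0.287 with an estimated correlation). PMVK had log2 differences of -0.54 to -0.17 (SE 0.11), FADS1 -0.30 to -0.11 (SE 0.05) and HSD17B7 -0.27 to -0.10 (SE 0.06). With 2,4-D, FADS1 lost its call without unexposed replicate 2, 5 or 6 or 2,4-D replicate 2 (adjusted p up to 0.354), and PMVK without unexposed replicate 3, 4, 5 or 6 or 2,4-D replicate 1 (up to 0.420). In a fit of the compared groups alone neither passed (0.104 and 0.116). HSD17B7 passed with 2,4-D without unexposed replicate 1 or 2,4-D replicate 2 (down to 0.0229). With glyphosate+2,4-D, FADS1 passed without replicate 2 of that group (0.0299) and PMVK without unexposed replicate 1 or 2 (down to 0.0298). After rescaling to TPM, FADS1 also passed with glyphosate, AMPA and glyphosate+2,4-D (limma adjusted p = 1.91e-04 to 0.00142). PMVK then passed with AMPA and glyphosate+2,4-D (0.0185 and 0.00879) and HSD17B7 with 2,4-D and glyphosate+2,4-D (0.0122 and 0.0230).

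**Figure D3:**
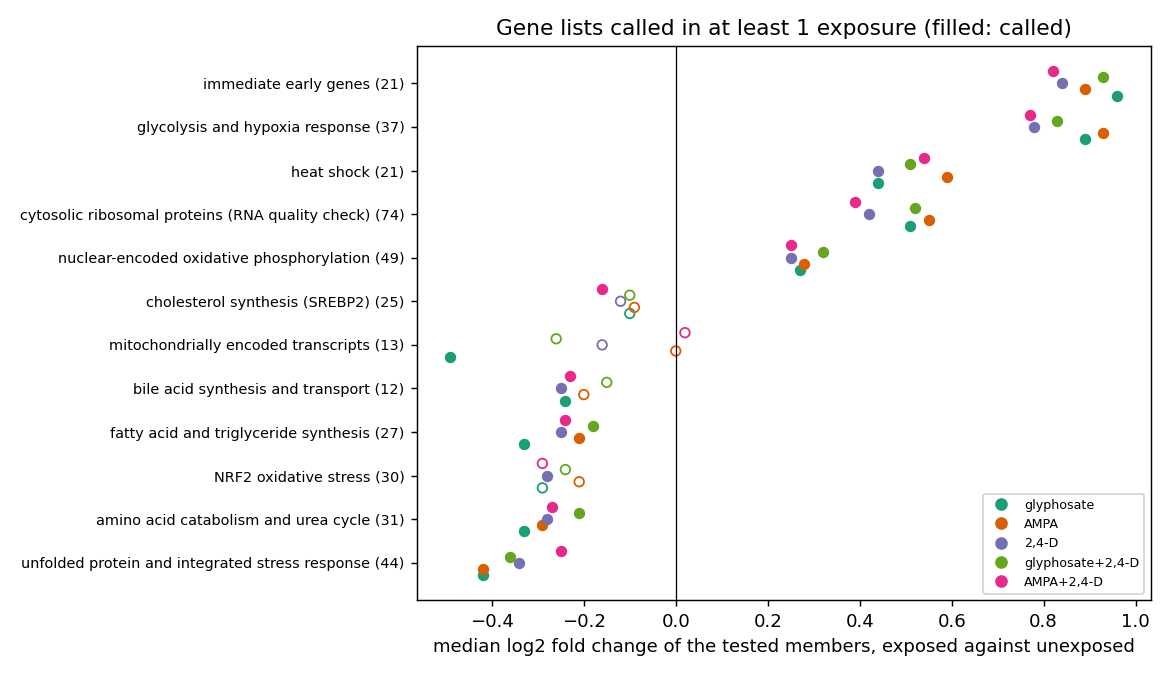
Median log2 fold change of the tested members of 12 gene lists (rows, number of members in brackets) for each of 5 exposures against unexposed cells; filled points mark pairs called with the preset correlation. Medians of immediate early genes lie at 0.82 to 0.96 and those of the unfolded protein list at -0.42 to -0.25; after rescaling to TPM the medians keep these signs.

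No call was made for the other 13 lists tested. Phase I and phase II xenobiotic metabolism had medians of -0.41 to -0.23 and -0.24 to -0.16, with camera adjusted p of at least 0.0814 and 0.0761. Lists with positive medians were hepatocyte secreted and identity genes (0.28 to 0.35), p53 targets (0.15 to 0.18), metallothioneins (0.15 to 0.19), acute phase genes (0.07 to 0.20), cell cycle (0.04 to 0.15), PPAR alpha targets (0.04 to 0.15) and histones (0.21 to 0.35). PPAR alpha, cell cycle and acute phase medians turned negative in at least 1 exposure after rescaling to TPM, down to -0.13, -0.08 and -0.03, and the histone list was then called higher in 5 exposures. Interferon genes (-0.13 to -0.01) and nuclear noncoding RNA (-0.14 to -0.06) had negative medians, and with AMPA+2,4-D the mean of the latter was positive (0.03) while camera put it lower, without a call. Cholangiocyte and stellate cell markers had medians of 0.05 to 0.13 (down to -0.05 after rescaling to TPM) and 0.03 to 0.33, and endothelial and leukocyte markers had 3 tested members each. The most abundant markers of other cell types were LYZ (537 FPKM), FN1 (505) and SPP1 (406). Against unexposed replicates 1 to 3 alone, the p53, cell cycle, hepatocyte, phase I and stellate lists were each called in 5 exposures.

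Glyphosate with 2,4-D was next set against glyphosate alone, which asks what 2,4-D added. No gene passed by limma, with 0 calls by voom and 1066 of 13405 genes at an unadjusted p under 0.05. The genes with the smallest p, which did not pass, were higher for TECTB (0.73 ± 0.13, log2, SE), ALDH1B1 (0.26 ± 0.05) and ASS1 (0.33 ± 0.06), and lower for PFKFB3 (-0.41 ± 0.08), ARFGEF3 (-0.28 ± 0.05) and ABCF3 (-0.21 ± 0.04). ASS1 stood at 58.1 ± 2.82 FPKM in unexposed cells (SD, n = 6), 26.5 ± 1.83 with glyphosate and 33.5 ± 1.65 with the mixture (SD, n = 3). The smallest adjusted p was 0.117. In 20.3% of genes the groups did not overlap, where chance gives 10%, and the 95% interval of the difference lay within 1.5-fold for 85.4% of genes. Without unexposed replicates 1 to 3, which entered through the shared spread alone, 25 genes passed, and without replicates 4 to 6 there were 8. TECTB and ARFGEF3 passed in both cases (limma adjusted p = 0.0252 to 0.0368). With array weights, whose estimation stopped before convergence, all genes named for this comparison passed (limma adjusted p = 0.0112 to 0.0324).

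Against 2,4-D alone, the same mixture had SNAI1, a transcription factor gene of epithelial-mesenchymal transition, at 4.32 ± 0.244 and 2.66 ± 0.160 FPKM (SD, n = 3), a log2 difference of 0.54 ± 0.11 (SE) that did not pass. The other genes with the smallest p, none of which passed, were C1orf53 (0.92 ± 0.20), the glutathione transferase gene GSTA4 (0.43 ± 0.10), NCR3LG1 (-0.20 ± 0.04), ARFGEF3 (-0.22 ± 0.05) and TNKS (-0.16 ± 0.04). C1orf53 rested on 6 to 43 reads per library of the pair of groups. Limma called 0 genes and voom 0, with 578 at an unadjusted p under 0.05 and a smallest adjusted p of 0.550. The groups did not overlap in 12.5% of genes, where chance gives 10%, and the 95% interval lay within 1.5-fold for 86.4% of genes.

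AMPA with 2,4-D differed from AMPA alone in genes that included the glutathione transferase gene GSTA2. This gene stood at 5.61 ± 1.47 FPKM with the mixture and 2.35 ± 0.227 with AMPA (SD, n = 3), a log2 difference of 0.96 ± 0.22 (SE). MT-ATP8 (0.74 ± 0.15) and the phosphate transporter family gene SLC17A2 (0.71 ± 0.14) were also higher. ATG10 (ENSG00000152348, chromosome 5, 81972025 to 82276857), an autophagy conjugation enzyme, had a log2 difference of -1.50 ± 0.35, CCDC152 -1.36 ± 0.34 and the chloride channel gene BEST1 -0.92 ± 0.23. ATG10 lay at 1.49 and 1.32 FPKM in AMPA+2,4-D replicates 1 and 3 and at 8.74 in replicate 2, against 9.19 to 10.3 with AMPA, and CCDC152 and BEST1 had the same order. Exons of ATG10, CCDC152 and BEST1 overlap RPS23, SELENOP and FTH1 on the opposite strand, partners named after their values were seen, at 222 to 621 FPKM. Reads of 98 such opposite-strand genes were 1.05% and 1.02% of their partners' reads in AMPA+2,4-D replicates 1 and 3, and 1.35 to 1.66% in the other 19 libraries. Limma called 363 genes (voom 441), 94 higher and 269 lower, 36 by at least 2-fold, with 25.5% of genes free of overlap, where chance gives 10%. After rescaling to TPM 69.5% of 151 called genes were higher, against 25.9% before it, and 69.2% of 201 with the same genes tested. No gene was called without AMPA+2,4-D replicate 1 or 3 (limma), 57, 65 and 26 without AMPA replicate 1, 2 and 3, and 836 without AMPA+2,4-D replicate 2. The calls of GSTA2, ATG10, CCDC152 and BEST1 were each lost without any of those libraries except AMPA+2,4-D replicate 2 (adjusted p up to 0.172, 0.188, 0.211 and 0.202), and those of MT-ATP8 and SLC17A2 except also AMPA replicate 1 (up to 0.128). In a fit of the compared groups alone none of these 6 genes passed (adjusted p of 0.0825 to 0.217).

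**Figure D4:**
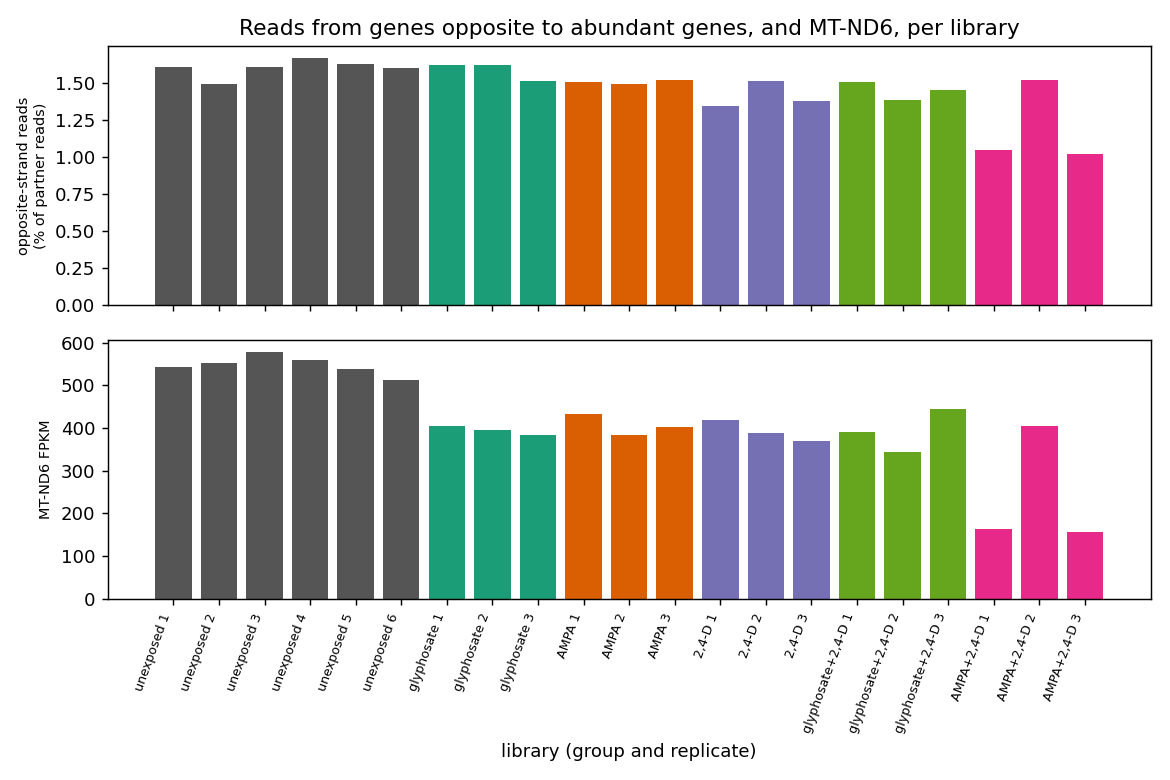
Reads of 98 genes lying opposite to far more abundant genes, as a percentage of the reads of their 95 partners (upper bars), and FPKM of MT-ND6, the light-strand mitochondrial gene (lower bars), for each of 21 libraries. AMPA+2,4-D replicates 1 and 3 stand lowest, at 1.05% and 1.02% and at 163 and 156 FPKM.

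When AMPA with 2,4-D was set against 2,4-D alone, no gene passed by limma (0 by voom, 1415 at an unadjusted p under 0.05, smallest adjusted p 0.191). The genes with the smallest p, which did not pass, were PAK1IP1 (0.22 ± 0.04, log2, SE), the endoplasmic reticulum co-chaperone gene DNAJB11 (0.18 ± 0.03), MARCH7 (0.22 ± 0.04), the collagen gene COL18A1 (-0.30 ± 0.06), ATAD3A (-0.25 ± 0.05) and the NF-kB subunit gene NFKB2 (-0.21 ± 0.05). DNAJB11 stood at 49.3 ± 1.30 FPKM with the mixture and 43.5 ± 0.913 with 2,4-D (SD, n = 3). The groups did not overlap in 17.3% of genes, where chance gives 10%, and the 95% interval lay within 1.5-fold for 85.4% of genes. Without AMPA+2,4-D replicate 2, limma called 223 genes, and all 6 of these named genes passed, with adjusted p of 0.00137 to 0.0449.

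AMPA was compared with glyphosate, from which it differs by lacking the carboxymethyl group on nitrogen, at molar concentrations that differed (34 and 5.6 µM). Across the genes that led each exposure the readouts lay side by side: DKK1 at 40.2 ± 6.88 and 37.5 ± 5.37 FPKM, IGFBP3 at 23.9 ± 3.53 and 23.9 ± 2.92, and UCP2 at 3.85 ± 0.371 and 3.68 ± 0.501 (SD, n = 3). The genes with the smallest p, none of which passed, were higher with AMPA for the clotting factor gene F5 (0.18 ± 0.04, log2, SE), TTC9C (0.20 ± 0.06) and POLR2G (0.18 ± 0.05), and lower for MBIP (-0.34 ± 0.07), the mitochondrial protease gene CLPP (-0.26 ± 0.06) and HSF4 (-0.33 ± 0.08). Limma called 0 genes, as did voom, with 410 at an unadjusted p under 0.05, a smallest adjusted p of 1.00 and 11.1% of genes free of overlap, where chance gives 10%. The 95% interval of the difference lay within 1.5-fold in FPKM + 1 for 86.8% of genes and within 2-fold for 95.1%, reaching a median of 0.183 to either side on the log2 scale.

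The interaction of glyphosate and 2,4-D asks whether the mixture departed from the sum of the single effects on the log2 scale. For genes higher with each compound the mixture lay below that sum, by -3.01 ± 0.44 for DKK1, -2.96 ± 0.44 for IGFBP3 and -2.45 ± 0.26 for AKAP12 (log2, SE). For genes lower with each it lay above the sum, by 2.11 ± 0.32 for GSTA1, 2.08 ± 0.25 for UCP2 and 1.94 ± 0.29 for GSTA2. DKK1 stood at 4.80 ± 2.74 FPKM in unexposed cells (SD, n = 6) and 37.5 ± 5.37, 31.2 ± 1.81 and 28.1 ± 0.650 with glyphosate, 2,4-D and both (SD, n = 3). Limma called 4498 genes, 2094 higher and 2404 lower than the sum. Of these, 4494 (99.9%) had an interaction opposite in sign to the mean change over the 5 exposures, and 0 were also called between the mixture and either compound by limma. After rescaling to TPM 57.6% of called interactions were positive, against 46.6% before it.

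The interaction of AMPA and 2,4-D had the same form. It was -2.92 ± 0.44 for IGFBP3, -2.78 ± 0.44 for DKK1 and -2.64 ± 0.26 for AKAP12, and 1.95 ± 0.32 for GSTA1, 1.94 ± 0.29 for GSTA2 and 1.85 ± 0.32 for DKK4 (log2, SE). DKK4 stood at 10.3 ± 3.41 FPKM in unexposed cells (SD, n = 6) and 2.50 ± 0.439, 2.60 ± 0.373 and 3.29 ± 1.39 with AMPA, 2,4-D and both (SD, n = 3). Limma called 4921 genes, 2262 higher and 2659 lower than the sum, of which 4870 (99.0%) were opposite in sign to the mean change. Of the 4921, 307 were also called between the mixture and AMPA and 0 between the mixture and 2,4-D. After rescaling to TPM 68.1% were positive, against 46% before it.

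The 5 exposures differed in largely the same genes from the same unexposed libraries. Of 13405 genes, 4504 (33.6%) were called in the same direction in all 5, 2438 higher and 2066 lower, while 25 were called in opposite ways in any pair. The genes with the largest smallest change were IGFBP3 (2.54 to 2.91, SE 0.29), DKK1 (2.47 to 2.96, SE 0.29), AKAP12 (2.11 to 2.48, SE 0.17), HSPA6 (2.06 to 2.57, SE 0.16) and SLC2A3 (1.92 to 2.28, SE 0.10), and KLHDC7B (-1.72 to -1.46, SE 0.10), UCP2 (-1.83 to -1.37, SE 0.17), SLC16A13 (-1.55 to -1.31, SE 0.11), FNDC4 (-1.68 to -1.28, SE 0.26) and AKR1B10 (-1.61 to -1.22, SE 0.38). In fits of the compared groups alone AKR1B10 did not pass in the mixtures with glyphosate and with AMPA (limma adjusted p = 0.0673 and 0.0815), nor in the latter without its replicates 1 and 3 (0.132). After rescaling to TPM 31.4% of 4725 such genes were higher, against 54.1% before it. Simulated exposures without effect, set against shared simulated unexposed libraries, gave a mean of 0.1 genes. The simulated values were independent, so the difference between the unexposed sets and the correlation between genes were left out. The simulation is thus a reference for independent noise alone. Correlations of fold changes, across genes, which are not independent replicates, were 0.817 to 0.930 over the 10 pairs of exposures, and 0.382 to 0.390 in the simulation. Their covariance was 0.113 to 0.148, against a simulated 0.00815 to 0.00836. Genes called higher by both exposures of a pair numbered 2764 to 3324, where independent lists give 850 to 1040, and those called lower 2369 to 2934, where independent lists give 687 to 834. With each exposure of a pair set against its own 3 unexposed libraries, the correlation was 0.559 to 0.863 over 10 splits, and 3205 to 3271 genes were called the same way in all 5 exposures against both sets of each split.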

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

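Chosen only after the result was seen were the tests of the shared unexposed libraries, batch, opposite-strand reads, GC and length, and NRF2; the splits were planned. In 5 of 99 groups of unexposed values 1 library lay far from the rest, and chance gives about 1 in 20. The gap was 0.651 of the range for ALDH1B1 (replicate 5, 34.5 FPKM) and CLPP (replicate 3, 11.2), 0.671 for COL18A1 (replicate 1, 11.4), 0.642 for MT-ATP6 (replicate 6, 3276) and 1 for CYP3A4 (replicate 2, 0.0512 FPKM, others 0). The interaction term passed in 4498 genes for glyphosate and 2,4-D and in 4921 for AMPA and 2,4-D. A shift shared by all exposed libraries gives this form too, since 99.9% and 99.0% of these were opposite in sign to the mean change, so they are not shown to be effects of one compound on the other.

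Each exposure gave the largest count of 84 splits of its libraries and the unexposed ones (1 of 84 each). Counts for glyphosate, AMPA and 2,4-D were 7069 (highest other 4394), 7083 (4436) and 6379 (4337). Those for the mixtures with glyphosate and with AMPA were 6445 (4503) and 6758 (4187). These splits treat single libraries as interchangeable, but the sets of unexposed libraries differed from each other in 4239 genes. The share of 1 in 84 thus holds for single libraries dealt at random. A chance difference between sets of libraries is not excluded by it. The overlap of 4504 genes was reached in 1 of 100 draws, the real grouping itself (highest other 0). The other draws shuffled all 21 libraries, which mixed exposed with unexposed ones. The result thus shows that exposed libraries differed from unexposed ones as a block, which a batch would give too. The interactions were reached in 2 of 100 draws each, the real grouping included, a share under the 0.05 set in advance. The highest other draws gave 5976 and 5163, above the real 4498 and 4921, so chance is not excluded for these counts. That random draws gave so many genes points to a structure of the samples. For the 46 list calls chance is not excluded (14 of 100 draws, highest other 59, median of the others 36). For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. There the real and highest other counts were 363 and 3 for AMPA+2,4-D against AMPA (1 of 10 as large) and 0 and 13 against 2,4-D (10 of 10; voom 0, with 1415 at an unadjusted p under 0.05). They were 0 and 0 for glyphosate+2,4-D against either component and AMPA against glyphosate (10 of 10 each; limma and voom called 0 genes, with 1066, 578 and 410 at an unadjusted p under 0.05).

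All 5 exposures differed from unexposed cells in the same direction in 4504 genes. Chance values of the shared unexposed libraries are argued against, since fold changes taken against separate sets of 3 unexposed libraries correlated at 0.559 or more. A GC or length trend as the whole cause is too, since 4753 genes were called the same way after its removal. A batch that separates exposed from unexposed libraries cannot be told apart from exposure. The unexposed sets themselves differed in 4239 genes, and no exposed library is known to share a batch with either; a response shared by the exposures stays open beside it.

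AMPA+2,4-D replicates 1 and 3 lay apart from replicate 2. Fewer reads from the strand opposite to abundant genes is a candidate explanation for part of this, since 98 such genes had a median log2 difference of -0.404, against 0.02 for other genes, and 15 of them were among the 269 genes lower than with AMPA (Fisher's exact p = 9.62e-10 over genes). These 15 include ATG10, CCDC152 and BEST1, whose values were seen before the test was chosen, and genes are not independent replicates. The Fisher p-value is thus no separate support. Fewer opposite-strand reads do not account for the 94 genes that were higher. A GC or length trend may contribute: after its removal 48 genes were called in place of 363, as the median size of their change went from 0.28 to 0.22 with a median SE of 0.06 before and after. No biological explanation was tested, since the labels give these 3 libraries the same exposure.

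The NRF2 list was called lower in 1 of 5 exposures, and in 0 with an estimated correlation (camera). A difference between unexposed replicates 1 to 3 and 4 to 6 may account for this, since the list medians against replicates 4 to 6 were at least 0.01. Of 5 members chosen after their values were seen, means in unexposed replicates 1 to 3, 4 to 6 and exposed cells were 119, 38.5 and 65.2 FPKM for TXNRD1, 22.9, 6.90 and 7.19 for GCLM, 331, 222 and 239 for NQO1, 128, 36.3 and 25.0 for AKR1B10 and 38.9, 19.7 and 13.9 for HMOX1. Against replicates 4 to 6 the first 3 of these were higher in exposed cells and the other 2 lower, so they settle no direction, and a change of NRF2 activity on exposure was not separated from the difference between the unexposed sets.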

How the results depend on the processing

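Chosen only after the data were seen were the tests with voom, without either set of unexposed replicates, without AMPA+2,4-D replicates 1 and 3, with the GC and length trend removed, and with TPM on the same genes. Counts for the 5 exposures, both interactions and the overlap stayed within 1.5 times under every alternative run, except AMPA+2,4-D without its replicates 1 and 3 (3565 in place of 6758), where fewer libraries remain. With 1 library left out they were 6038 to 7115 (glyphosate), 6102 to 7188 (AMPA), 5239 to 6508 (2,4-D), 5452 to 6554 and 5540 to 6825 (mixtures), 3811 to 4721 and 4175 to 5120 (interactions) and 4108 to 4649 (overlap).

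AMPA+2,4-D against AMPA (363 genes) was the least stable count. It gave 183 without a filter, 151 with TPM (201 with the same genes tested), 1364 with arrayWeights and 48 with the GC and length trend removed. Without unexposed replicates 1 to 3 it gave 1161, and without 4 to 6 it gave 1074. With the replicate block, which used replicates 1 to 3 and so also left out unexposed replicates 4 to 6, it gave 921. With only the groups of the contrast it gave 1, and without AMPA+2,4-D replicates 1 and 3 it gave 0 (limma; 2446 genes at an unadjusted p under 0.05 with all libraries, voom 441). Leaving out 1 library gave 0 to 836: 57, 65 and 26 without AMPA replicate 1, 2 and 3, 0 without AMPA+2,4-D replicate 1 or 3 and 836 without replicate 2. AMPA+2,4-D against 2,4-D (0 genes) gave 1 with the replicate block, 214 with arrayWeights and 10 without unexposed replicates 1 to 3, and 0 to 223 with 1 library left out, 223 being without AMPA+2,4-D replicate 2. Glyphosate+2,4-D against glyphosate (0) gave 34 with arrayWeights and 25 without unexposed replicates 1 to 3. It gave 8 without unexposed replicates 4 to 6 and 10 with the block, which lacks them too. Against 2,4-D (0) the same mixture gave 1 with the block. The 46 list calls became 70 without a filter, 73 with TPM, 17 with an estimated correlation, and 44 to 54 with 1 library left out. They became 83 without unexposed replicates 4 to 6 and 80 with the block, which lacks the same libraries. With TPM and the same genes tested as in the main fit, 13 list results gained a call and 1 lost it. Unexposed libraries enter comparisons between exposures through the shared spread alone. Leaving them out could thus move those counts only through the estimate of that spread and the number of libraries behind it. Where exposed libraries were left out fewer libraries remained, yet counts both fell and rose. For the other changes the cause was not tested. Replicate numbers did not pair the libraries: over 45 same-number pairs the median r was -0.004, and 8 of 18 libraries correlated best with their own number.

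No named gene reversed under any alternative run, where a reversal is a change of sign with a call in at least 1 of the compared fits. Changes of sign without a call in either fit were not counted. With 1 library left out 3142 named-gene results kept their call or lack of it, 62 lost the call and 18 gained it. One list result reversed: the NRF2 list with 2,4-D had a median of 0.01 without unexposed replicates 1 to 3 (adjusted p = 0.941); the sets of unexposed libraries differ in this list, as weighed above. Counts of at least 2-fold for the 5 exposures were 218 to 343, and became 598 to 827 with a pseudocount of 0.1, 660 to 930 with voom and 564 to 845 with TPM, since a pseudocount of 1 shrinks folds of genes with low values. Depth limits genes of few reads, such as CYP3A4 and PDK4.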

Other observations

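The list here was chosen only after CYR61, ANKRD1 and IGFBP3 had been seen to rise; its prediction and its splits were written before its result was seen. Those genes are targets of the TEAD transcription factors, so higher activity of YAP and TEAD in exposed cells was a hypothesis. It was tested on other targets, with those 3 genes and CCN2 left out, of which 13 passed the filter. The prediction was a list median above 0.2 and a call with an estimated correlation in every exposure, and it was not met. Medians were 0.12 to 0.26, with camera p of 0.0478 to 0.0854 with an estimated correlation, under 0.05 in 1 exposure, in 3 against unexposed replicates 4 to 6 and in 5 against replicates 1 to 3. The value of 0.12 did not reach the level that would have excluded the hypothesis. In 4 of 100 draws of the groups, the real one included, as many exposures passed (real 1, highest other 1). That share is under the 0.05 set in advance, but random draws tied with the real count of 1, so chance is not excluded. AXL rose by 1.13 to 1.54 (SE 0.09) and CRIM1 by 0.40 to 0.62 (SE 0.05), while AMOTL2 had -0.25 to -0.12 (SE 0.05), genes picked after their values were seen. A contribution of YAP and TEAD activity for some targets stays open, and a batch difference was not separated from it.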
